A study of Mus musculus with 32 samples.

How the data were processed

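The series holds 32 sample records of stromal vascular fraction cells from epididymal fat. Records of one source name differ only in sample index and lane, 4 indices and 2 lanes, so the 8 records of a source name were taken as runs of 1 library, and each of the 4 groups (normal or high fat diet, labelled WT or CD169-DTR) has 1 library. Per the submitters' processing notes, reads were processed with Cell Ranger 3.1.0 against the mm10 genome, and the labels state a target of 7000 cells and an estimated multiplet rate of 5.4%. The deposited matrix holds raw UMI counts per gene and barcode, whole numbers for 31053 genes, pooled over the 4 libraries and listed per the file headers with a number at the end of each barcode. The number was mapped to a library by the order of the deposited aggregation list, which no other file states independently, and whether reads were subsampled to equal depth when the libraries were pooled is not given.

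Barcodes with at least 300 genes and at most 10% mitochondrial UMIs were kept, which removed 11.5% of barcodes in normal diet labelled WT, 9.72% in normal diet labelled DTR, 22.5% in high fat diet labelled WT and 9.33% in high fat diet labelled DTR. Doublets were called per library with Scrublet in scanpy 1.11.5 at the expected rate of the labels. The automatic threshold marked 1.31%, 0.690%, 1.29% and 1.37% of cells, all above the minimum of 0.5%, and these were removed. Counts were scaled per cell and log transformed, and 2000 variable genes, 30 principal components and 15 nearest neighbours gave a graph that was clustered with leidenalg 0.10.2 at resolution 1.5 and seed 1, with scikit-learn 1.9.0, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 under Python 3.11.15. A cluster was called immune when its mean CPM of Ptprc was above the highest cluster mean divided by 10. Clusters were named from marker genes set before the data were examined, and called "like" that class; a cluster with under 3 detected markers, with more markers of another class among its leading genes, with low UMI counts and none of the markers leading, or with markers of more than 1 class stayed unnamed. Unnamed clusters held 22.3%, 11.6%, 13.8% and 5.33% of the cells in the library order above. The thresholds for detecting a marker were set after the clusters were seen. All 13 unnamed clusters held markers of a reported class. Among them were one with macrophage and type 2 dendritic markers (16.6%, 1.72%, 13.2% and 1.80% of immune cells), one with monocyte and macrophage markers (3.06%, 4.99%, 2.32% and 4.13% of immune cells), and pairs with endothelial and adipocyte markers (7.35%, 6.05%, 3.54% and 0.412% of non-immune cells in the first, 7.22% and 2.88% in the second, which had no cells in high fat diet). Smaller ones had endothelial and pericyte markers (2.28%, 0.807% and 0.541% of non-immune cells, none in high fat diet labelled DTR), and T and type 2 dendritic markers (2.56%, 1.99%, 2.83% and 0.626% of immune cells). A further one had NK markers and, among its leading genes, Ccl5, which was listed as a migratory dendritic marker (1.19%, 1.50%, 1.44% and 0.737%). Others had NK and T markers (0.803%, 1.40%, 0.736% and 1.66%), and B and plasma markers (2.07%, 0.161% and 0.847%, none in high fat diet labelled DTR), and 4 more held up to 0.847% of the immune cells of a library. Plasmacytoid dendritic, mast and plasma cells had under 100 cells and were left out.

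Shares were computed within the immune or non-immune cells, since the 2 pools were mixed 1:1, with exact Clopper-Pearson intervals. For gene ratios, raw UMIs were summed per library and class and divided by the total of the class (CPM). A gene needed 50 UMIs over the 2 libraries and a class 50 cells in each. Levels carry exact Poisson intervals, and log2 ratios carry conditional exact binomial intervals. All intervals are at 95% and cover counting error only, not variation between mice. For a gene with 0 UMIs the floor of 3 UMIs in that library gives the bound. With 1 library per group no test was run, and no p-values are given; counts of genes whose counting intervals exclude 0 describe these libraries only.

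The 24 gene lists set before the data were examined were collagen and matrix, adipogenic, Dpp4-high progenitor, inflammatory chemokine and cytokine, contractile and TGF-beta response, endothelial junction, leukocyte adhesion, angiogenic, endothelial lipid handling, hypoxia and glycolysis, interferon response, MHC class II, MHC class I, immediate early, cell cycle, oxidative stress and metallothionein, resident macrophage, lipid-associated macrophage, monocyte-derived, engulfment of dead cells, cytotoxic and exhaustion, regulatory T, type 2 cytokine, and B1 against B2. Each was read in the classes named for it where at least 5 members were measured, as the median log2 ratio with an interval from 1000 Poisson draws. Its percentile among 10000 random lists of the same size matched on mean expression was computed as a description of these libraries. Genes were named by a rule also set in advance. Genes were ordered by the bound of the counting interval nearest to 0, and in each main comparison the 5 highest and 5 lowest were taken in fibroblast and progenitor-like cells, 4 and 4 in endothelial-like cells and 3 and 3 in NK-like cells, the immune class whose smallest library had the most cells. For the diet comparison labelled DTR 2 and 2 were taken, for both diets 5 and 5 in fibroblasts, and 2 leading members per list; a few of the genes so taken are not reported here. Mitochondrial, ribosomal protein, haemoglobin, immune receptor segment, Xist, Y-linked, Malat1 and provisional genes, and genes whose level in the class was more than 10 times under their level in another class of that library, were not ranked. Other resident macrophage genes over all immune cells were named after Siglec1 was seen.

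The ratio and list computations were tested on simulated data drawn from the real class sums with 200 changed genes. In fibroblasts in normal diet, over 11105 genes, 85.1% of changes of 0.5, 100% of changes of 1 and 100% of changes of 2 on the log2 scale had intervals that excluded 0, and the intervals held the true value for 95.5% of genes. In NK-like cells of the same comparison, over 5909 genes, these were 48.6%, 96.7% and 100%. The simulated counts were Poisson draws, the model that the intervals assume, without variation between mice, preparations or cell mix. Coverage near 95% was thus built in, and these figures check the computation only. Alternatives set in advance were looser and stricter cell filters, doublets kept, other clustering resolutions, shares of all cells, TMM factors (edgeR 4.0.16 in R 4.3.3), equal weight per cell, thinning to a fixed depth, a minimum of 200 UMIs, stress, mitochondrial and ribosomal genes left out of the totals, and Siglec1 over all barcodes. Alternatives added after seeing the data were wider phagocyte and endothelial sets, the macrophage class without its cluster of low UMI counts, and Siglec1 over immune cells. Gene positions are from GENCODE M21 on GRCm38, 1-based, and figures were drawn with matplotlib 3.10.9.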

Results

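Single-cell RNA sequencing (10x Genomics 3′ v3) was carried out on stromal vascular fraction cells, the cells of fat tissue that remain once mature adipocytes are removed, from the epididymal fat of C57BL/6 mice. Wild-type (WT) and CD169-DTR mice were kept on a normal diet or a high fat diet for 16 weeks, and all received diphtheria toxin for 7 days. CD169-DTR mice carry the diphtheria toxin receptor at the locus of Siglec1, the gene of the macrophage surface lectin CD169, so that the toxin is meant to remove CD169-positive tissue resident macrophages. CD45-positive and CD45-negative cells were sorted apart, with a large part of the F4/80-high cells and the Ly6C-high monocytes gated out, and mixed 1:1. How many mice were pooled per library is not given in the sources used here. The 4 groups each had 1 library, so there were no replicates within a group. No difference was tested, and every interval given here is a 95% interval for counting error. The files held 5701 barcodes and 37655128 UMIs for normal diet labelled WT, 4014 barcodes and 33390225 UMIs for normal diet labelled DTR, 6696 barcodes and 49142626 UMIs for high fat diet labelled WT, and 6292 barcodes and 64766718 UMIs for high fat diet labelled DTR. After the filters 4982, 3599, 5120 and 5627 cells remained in the same order, with median depths of 6159, 6870, 7776 and 9151 UMIs per cell.

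Siglec1, the gene whose locus carries the receptor, was higher in the libraries labelled DTR in both diets. Among the cells sequenced, this is against the direction that loss of CD169-positive cells would give. The sort had gated out many cells by macrophage and monocyte surface markers, so the levels cannot show whether ablation took place in the tissue. Over all cells, Siglec1 (ENSMUSG00000027322, chromosome 2, 131069220 to 131086765, minus strand, GRCm38) had 5 UMIs in normal diet labelled WT and 113 UMIs in normal diet labelled DTR, or 0.139 (0.0452 to 0.325) and 3.49 (2.88 to 4.2) CPM, the UMI counts of a gene scaled to the total UMIs of the cells. In high fat diet it had 51 UMIs, or 1.12 CPM (0.832 to 1.47), in the library labelled WT and 190 UMIs, or 3.03 CPM (2.61 to 3.49), in that labelled DTR. The log2 ratio of DTR over WT was 4.65 (3.39 to 6.30) in normal diet and 1.44 (0.99 to 1.91) in high fat diet. Within macrophage-like cells it was 3.35 (1.46 to 6.42), from 96 UMIs against 2, and 0.96 (0.48 to 1.47). Because Siglec1 in the sorted cells goes against the direction of the labels, groups are called by their label throughout. Each direction drawn between genotypes rests on those labels and on the order of the libraries in the deposited aggregation list. How the receptor was inserted is not given in the sources used here, so it is not known whether the counted 3′ end of Siglec1 lies in an altered part of the locus.

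Many other genes of resident macrophages went the opposite way to Siglec1 in high fat diet, where 13 of 14 measured genes of the list without Siglec1 were lower over all immune cells, and they divided in normal diet, with 7 of 13 lower and 5 higher. Over all immune cells, Timd4, a receptor for phosphatidylserine on dying cells, was lower in the libraries labelled DTR, with a log2 ratio of -2.42 (-2.68 to -2.16) in normal diet and -3.22 (-3.56 to -2.89) in high fat diet. Cd163, the haemoglobin scavenger receptor, had log2 ratios of -2.93 (-3.61 to -2.33) and -3.1 (-3.57 to -2.66), and Lyve1, a hyaluronan receptor, had -1.73 (-2.83 to -0.77) and -3.55 (-4.26 to -2.90). Cd209f was at least 9.90-fold lower in normal diet, where 39 UMIs stood against 0, and had a log2 ratio of -6.79 (-8.11 to -5.74) in high fat diet. Vsig4, a complement receptor, was at least 11.7-fold lower in high fat diet. Mrc1, the mannose receptor, had log2 ratios of -0.28 and -0.62, while Folr2, a folate receptor, was higher at 2.60 in normal diet and 0.13 in high fat diet.

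**Figure D1:**
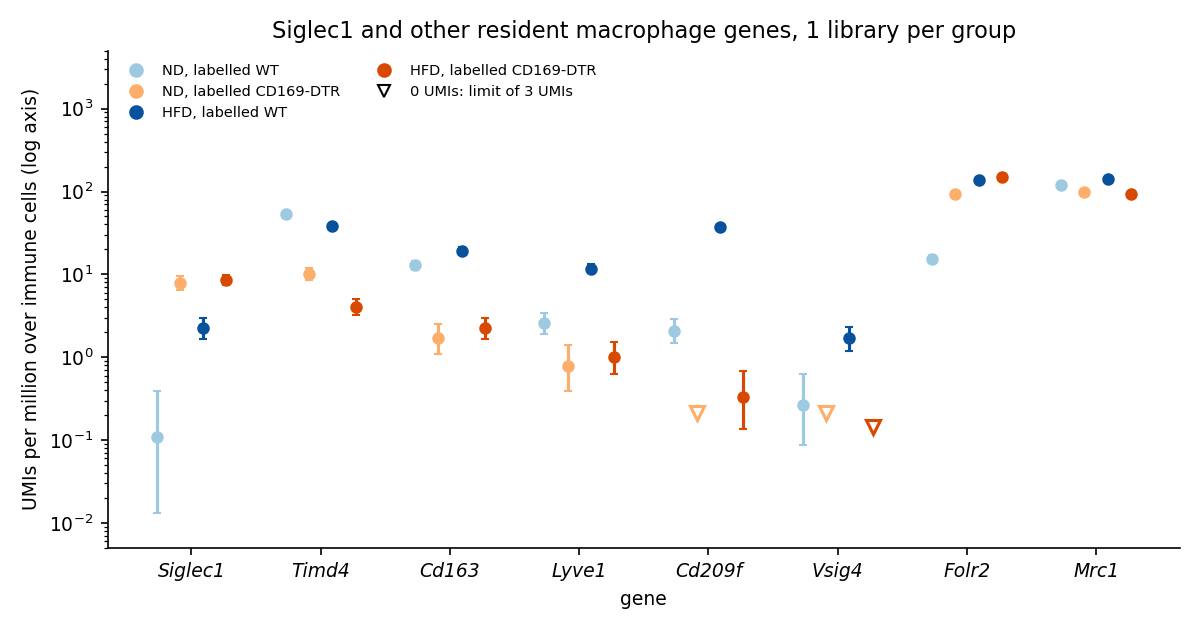
CPM over all immune cells (log axis) of Siglec1 and of other resident macrophage genes in the 4 libraries, with exact 95% Poisson intervals. Siglec1 had 7.83 and 8.57 CPM in the libraries labelled DTR against 0.107 and 2.23 CPM in those labelled WT, whereas Timd4 had 10.2 and 4.07 CPM against 54.2 and 37.8 CPM.

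The comparison of genotypes in normal diet asks how the other cells of lean fat differ where ablation of resident macrophages was intended. Fibroblast and adipocyte progenitor-like cells made up 64.6% (62.3 to 66.9) of the non-immune cells in the library labelled DTR and 47.7% (45.7 to 49.7) in that labelled WT. Vascular endothelial-like cells were lower, at 19.8% (17.9 to 21.7) against 27.8% (26.0 to 29.7). Among immune cells, NK-like cells were 2.88-fold higher, at 25.9% (23.9 to 28.0) against 8.99% (7.92 to 10.1), and neutrophil-like cells were 2.44-fold higher, at 4.94% against 2.03%. B-like cells were 3.02-fold lower, at 3.33% against 10.1%, and group 2 innate lymphoid-like cells 2.54-fold lower, at 2.84% against 7.23%. Type 1 conventional dendritic-like cells were 5.37% against 12.2%, type 2 conventional dendritic-like cells 6.44% against 8.60%, migratory dendritic-like cells 1.88% against 3.33%, and T-like cells 7.94% against 9.90%. Mesothelial-like cells had a log2 ratio of -0.26 (-0.66 to 0.14), which counting error alone covers. Macrophage-like cells were 26.0% (24.1 to 28.1) against 8.68% (7.63 to 9.83), a log2 ratio of 1.58 (1.35 to 1.82). That ratio was -0.20 with a looser cell filter and -0.25 with doublets kept. It was 0.23 over all mononuclear phagocyte clusters, which take in an unnamed cluster with both macrophage and type 2 dendritic markers that held 16.6% of the immune cells labelled WT and 1.72% of those labelled DTR. The gate on F4/80 and Ly6C can set the macrophage share and, through it, the other immune shares.

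**Figure D2:**
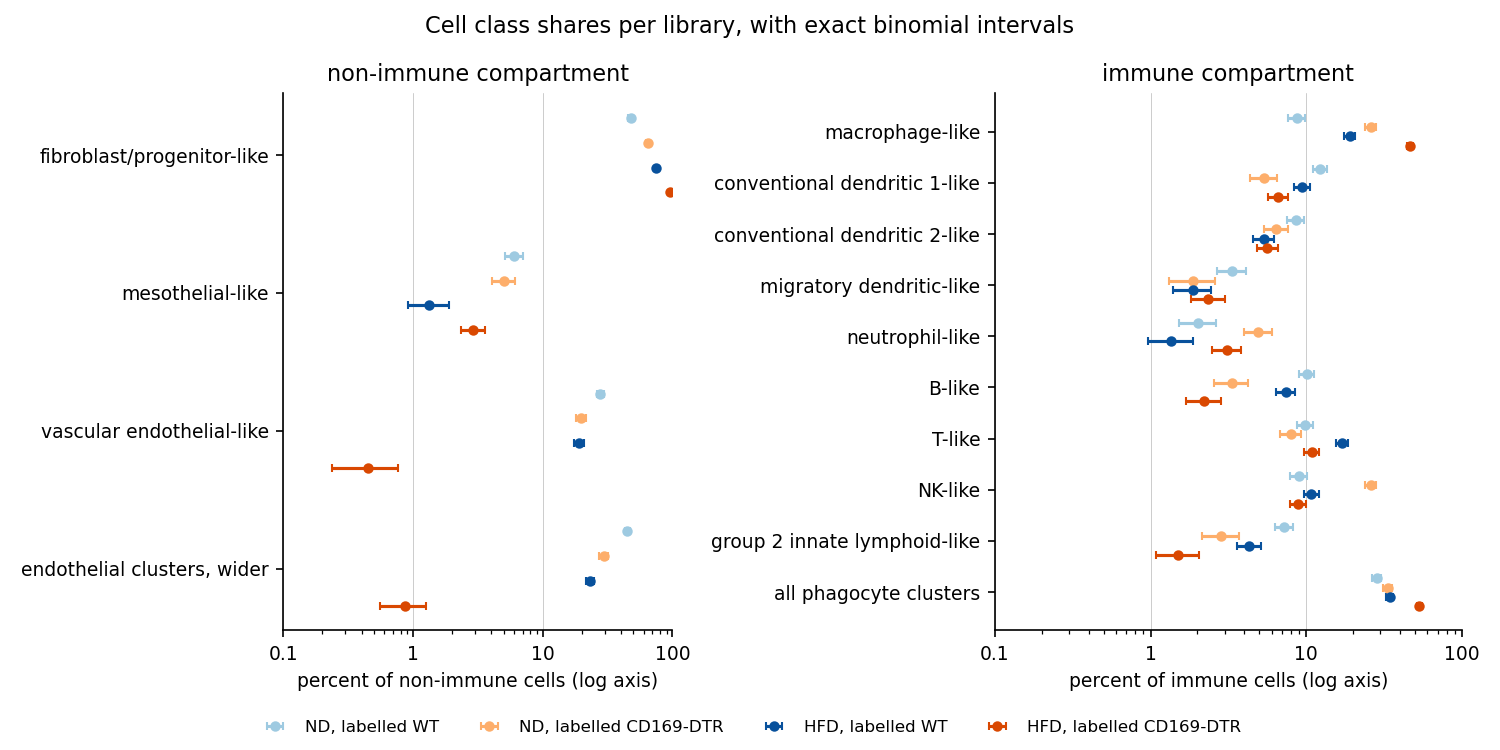
Share of each named class (percent of immune or of non-immune cells) in the 4 libraries, with exact 95% Clopper-Pearson intervals. Fibroblast and progenitor-like cells ran from 47.7% in normal diet labelled WT to 95.8% in high fat diet labelled DTR, where vascular endothelial-like cells were 0.446%.

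In fibroblast and progenitor-like cells of lean fat, genes of the interferon response, the cell cycle, contraction, matrix and inflammation were higher in the library labelled DTR. Of 22 measured interferon response genes 21 were higher beyond their counting intervals, with a median log2 ratio of 1.90 (1.78 to 1.99). Mx1, an antiviral GTPase, had 228 UMIs against 1, a log2 ratio of 7.34 (4.84 to 12.65), and Ifi44 (ENSMUSG00000028037, chromosome 3, 151730922 to 151749960, minus strand) was 51.0-fold higher. The 18 measured cell cycle genes had a median of 2.49 (2.12 to 2.74), with 17 higher, among them the cyclins Ccnb1 at 5.63 (3.75 to 8.69) and Ccna2 at 3.98 (2.71 to 5.63). Cluster 35, with the highest cell cycle score of these clusters, held 0.266% of the fibroblasts labelled WT and 1.60% of those labelled DTR. All 9 genes of MHC class I presentation were higher, with a median of 1.02 (0.89 to 1.05), led by H2-Q7 at 2.52 (2.29 to 2.77) and by Nlrc5, the transactivator of class I genes, at 2.45 (1.86 to 3.1). MHC class II genes, which present antigen to CD4 T cells, had a median of -0.95 (-1.03 to -0.85) over 6 genes, with H2-Eb1 at -1.04 and H2-Ab1 at -0.97. No background was subtracted, and H2-Ab1 stood at 93.0 and 47.5 CPM in fibroblasts labelled WT and DTR beside 46.2 and 66.6 CPM in NK-like cells, which should lack it.

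Inflammatory chemokine and cytokine genes had a median log2 ratio of 0.76 (0.75 to 0.77) in these fibroblasts, with 22 of 24 higher. Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700, minus strand), which encodes the acute phase protein serum amyloid A3, was 65.1-fold higher, at 449 CPM against 6.89 CPM. Cxcl5 (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624, plus strand), a chemokine for neutrophils, was 23.6-fold higher. Contractile and TGF-beta response genes had a median of 1.06 (1.00 to 1.17) with 10 of 13 higher. Tagln was 23-fold higher and Acta2, smooth muscle actin, 13.2-fold, although the Acta2 ratio was -0.41 when every cell was scaled to the same total. Collagen and matrix genes had a median of 0.76 (0.72 to 0.78) with 31 of 34 higher, led by Tnc (tenascin-C) at 4.76 (3.90 to 5.77) and by the matrix protease Mmp3 at 2.97 (2.46 to 3.52). Hypoxia and glycolysis genes had a median of 0.44 (0.27 to 0.52).

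Genes of early, Dpp4-high progenitors were lower, with a median log2 ratio of -0.44 (-0.62 to -0.40) and 9 of 13 lower, although Wnt2 was higher at 2.39 (1.55 to 3.35) while Pi16 was lower at -1.24. The oxidative stress and metallothionein list had a median of -0.38 (-0.43 to -0.32), the adipogenic list 0.06 (-0.08 to 0.20) and the immediate early list -0.08 (-0.12 to -0.02). By size alone, the cell adhesion gene Chl1 at 6.87 (4.37 to 12.18) and the non-classical class I gene H2-M2 at 5.27 (4.28 to 6.49) joined Saa3, Mx1 and Ifi44 as the highest. The lowest were the chemokine gene Ccl21a (its copy ENSMUSG00000094686) at -6.73 (-12.05 to -4.2), Tmem114 at -5.40 (-7.71 to -3.81), Pgf, a growth factor of the VEGF family, at -3.70, Ackr4, a scavenger receptor for chemokines, at -3.67, and the complement gene C7 at -2.68. The Ccl21a ratio rests on 1 UMI against 75. The diet ratio labelled WT, which rests on the same 75, was 0.01 (-4.25 to 5.89) with doublets kept. The largest fibroblast cluster differed between the 2 libraries, with cluster 9 holding 43.6% of the fibroblasts labelled WT and cluster 4 holding 61.5% of those labelled DTR. The median of all genes in the class was 0.11 and TMM scaling shifted every ratio by -0.10, so that the group medians stand above or below that level.

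Vascular endothelial-like cells of lean fat had higher leukocyte adhesion and inflammatory genes in the library labelled DTR. All 7 measured adhesion genes were higher, with a median log2 ratio of 0.81 (0.55 to 0.95). Lrg1 (ENSMUSG00000037095, chromosome 17, 56119678 to 56122001, minus strand), a glycoprotein that promotes vessel growth, was 4.91-fold higher and Vcam1, the ligand of leukocyte integrins, 2.77-fold. Inflammatory genes had a median of 0.76 (0.56 to 1.02) with 11 of 14 higher, led by the monocyte chemokines Ccl7 at 2.37 and Ccl2 at 1.61. The interferon list went both ways, with 10 of 20 genes higher and 6 lower, a median of 0.23 (0.11 to 0.30), Ifit3 at 1.80 and Irgm1 at -1.63. Junction and barrier genes had a median of 0.16 (0.03 to 0.27) and lipid handling genes -0.15 (-0.20 to -0.05), with Rbp7 at -0.94 and Slc27a3 at 1.31. The angiogenic list had a median of 0.07 and a mean of -0.07. Prom1 was 11.8-fold and the phospholipid flippase Atp8b1 3.99-fold higher. Among the lowest, Timp4, an inhibitor of matrix proteases, was 3.79-fold lower, the cytochrome P450 gene Cyp1a1 7.17-fold, Igfbp3 4.23-fold, and Asb4, with 3 UMIs against 56, had a ratio of -3.13 (-5.45 to -1.5). Clusters 5 and 14 held these cells in both libraries. Adipocyte transcripts differed as well, at 477 CPM of the non-immune cells labelled DTR against 1099 CPM of those labelled WT.

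Macrophage-like cells of lean fat had higher interferon and monocyte genes and lower resident and MHC class II genes in the library labelled DTR. Interferon response genes had a median log2 ratio of 1.67 (1.51 to 2.24) with 19 of 21 higher, led by Irf7 (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481, minus strand), the transcription factor that amplifies type I interferon, at 3.12 (2.66 to 3.61) and Oasl2 at 2.83. Genes of monocyte-derived cells had a median of 1.39 (0.63 to 2.19). Chil3 had 1127 UMIs against 2, a ratio of 6.90 (5.05 to 9.95), and Plac8 was 6.33-fold higher. The resident list had a median of -1.13 (-1.29 to -0.91) with 7 of 12 lower, including Lyve1 at -4.10 (-5.21 to -3.11) and Gas6, a bridging ligand for engulfment receptors, at -3.20. This median was -0.47 (-0.57 to -0.38) with a minimum of 200 UMIs and -0.74 (-0.86 to -0.45) over all phagocyte clusters. All 7 MHC class II genes were lower, with a median of -1.11 (-1.14 to -1.07), H2-Eb1 at -1.19 and H2-Ab1 at -1.14. Lipid-associated macrophage genes had a median of 0.44 (0.38 to 0.52), with Apoe lower at -1.89 and Spp1 at 1.98 (1.67 to 2.30), which turned to -0.28 when every cell was scaled to the same total. The immediate early list had a median of 0.69 (0.57 to 0.73), and the engulfment list one of -0.37 (-0.47 to -0.18) that was 0.41 over all phagocyte clusters. Cluster 23, of low UMI counts, held 53.3% of these cells labelled WT and cluster 3 held 74.0% of those labelled DTR. The ratios rest on UMIs, however. Of 1384146 UMIs labelled WT, cluster 23 gave 85031 and cluster 22, with the highest cell cycle score of the macrophage clusters, 759331. Cluster 3 gave 3050899 of 6513790 UMIs labelled DTR. Summed over the interferon list, cluster 3 had 3519 CPM labelled WT and 5345 CPM labelled DTR, and cluster 22 had 1058 and 1753 CPM. Cluster 12 had 497 and 2755 CPM and cluster 31 had 1300 and 1537 CPM, while cluster 23 was lower, at 1858 and 857 CPM. The mix of clusters thus enters the interferon median beside differences within clusters.

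Conventional dendritic-like, T-like, NK-like and B-like cells of lean fat also had higher interferon genes in the library labelled DTR, with 11 of 13 in type 2 and 8 of 12 in type 1 dendritic-like, 8 of 10 in T-like, 8 of 11 in NK-like and 4 of 6 in B-like cells. The median log2 ratio of the interferon list was 2.18 (1.71 to 2.39) in type 2 conventional dendritic-like cells, where Irf7 was at 5.07 (4.12 to 6.23) and Zbp1 at 3.00, and 1.08 (0.80 to 1.25) in type 1 conventional dendritic-like cells. Cluster 32, whose second marker class is plasmacytoid dendritic, held 4% of the type 2 cells labelled WT and 33.3% of those labelled DTR. Cd7, Cd209d and Ly6c2 were leading genes both of it and of the plasmacytoid dendritic cluster 37. The 2 libraries may thus differ in the cell types within this class. The interferon median was 1.23 (0.94 to 1.56) in T-like cells, 0.91 (0.57 to 1.27) in NK-like cells, with Bst2 at 2.17, and 0.81 (0.46 to 1.13) in B-like cells. NK-like cells also had more Gadd45b, a stress-induced gene, at 2.91 (2.53 to 3.32), Ltb (ENSMUSG00000024399, chromosome 17, 35194439 to 35196320, plus strand), which encodes lymphotoxin beta, at 2.36 (2.00 to 2.73), and Dusp8, a phosphatase of MAP kinases, at 4.79 (2.26 to 10.11), and the immediate early list was at 0.45 (0.30 to 0.59) in them. Cluster 39, with Ltb among its leading genes, held 10.8% of the NK-like cells labelled DTR and none of those labelled WT. Ly6c2 and S100a6 were among the lowest NK genes, at -1.97 and -1.12. The cytotoxic list had a median of -0.02 and a mean of 0.15 in NK-like cells, with 3 of 10 genes higher and 5 lower, Ifng, the gene of interferon gamma, at 1.32 (0.87 to 1.79) and the chemokine gene Ccl3 at 1.2 (0.81 to 1.61), which was -0.46 under a stricter cell filter. In T-like cells that list had a median of 0.56 (0.34 to 0.99) with 6 of 9 genes higher, and cluster 10, which has cytotoxic genes among its leading genes, held 36.3% of the cells labelled WT and 48.6% of those labelled DTR. The type 2 cytokine list had a median of 0.31 (0.13 to 0.41) in group 2 innate lymphoid-like cells, and the B1 against B2 list one of 0.08 (-0.05 to 0.23) in B-like cells. TMM scaling shifted these ratios by -0.32 in type 2 dendritic-like cells, -0.15 in type 1, -0.13 in B-like, -0.12 in NK-like and -0.12 in group 2 innate lymphoid-like cells.

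The comparison of genotypes in high fat diet asks the same question of obese fat. Vascular endothelial-like cells were 42.5-fold lower in the library labelled DTR, with 13 of 2912 non-immune cells, or 0.446% (0.238 to 0.762), against 19% (17.4 to 20.6), and 26.9-fold lower with the unnamed endothelial clusters included. Fibroblast and progenitor-like cells were 95.8% (95.1 to 96.5) against 74.5% (72.7 to 76.2). Macrophage-like cells were 2.44-fold higher, at 46.6% (44.7 to 48.5) of immune cells against 19.1% (17.6 to 20.6), and neutrophil-like cells 2.27-fold higher, at 3.09% against 1.36%. B-like cells were 3.35-fold lower, at 2.21% against 7.40%, and group 2 innate lymphoid-like cells 2.85-fold lower, at 1.51% against 4.31%. T-like cells were 10.9% against 17%, type 1 conventional dendritic-like cells 6.59% against 9.42%, and NK-like cells 8.91% (7.87 to 10.0) against 10.8% (9.64 to 12.0). Type 2 conventional dendritic-like cells had a log2 ratio of 0.08 (-0.26 to 0.42) and migratory dendritic-like cells 0.33 (-0.22 to 0.89), neither beyond counting error. Mesothelial-like cells were 2.92% against 1.33%, a ratio of 1.13 that turned to -0.09 under a stricter cell filter and to -1.38 at a finer clustering, and the neutrophil ratio turned to -0.74 under the stricter filter. The macrophage ratio of 1.29 (1.14 to 1.44) was 0.55 with a looser filter. It was 0.62 over all phagocyte clusters, where the cluster with macrophage and type 2 dendritic markers held 13.2% of immune cells labelled WT and 1.80% of those labelled DTR. As in normal diet, the gate can set the macrophage share and, through it, the other immune shares, that of NK-like cells among them.

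Fibroblast and progenitor-like cells of obese fat again had higher interferon, cell cycle and contractile genes in the library labelled DTR. The interferon list had a median log2 ratio of 2.23 (2.20 to 2.35) with 21 of 22 genes higher, Ifi44 51.0-fold and Isg15, a ubiquitin-like modifier, 11.3-fold. The cell cycle list had a median of 2.42 (2.14 to 2.57) with 17 of 18 higher, led by Ccnb2 at 3.60 and Ccnb1 at 3.36, and cluster 35 held 0.335% of the fibroblasts labelled WT and 3.01% of those labelled DTR. Contractile and TGF-beta response genes had a median of 1.55 (1.5 to 1.60) with 13 of 14 higher. Cnn1, calponin 1, was at least 17.1-fold higher, with 101 UMIs against 0, and Ltbp2, which belongs to the TGF-beta binding protein family, 13.6-fold. MHC class I genes had a median of 0.69 (0.66 to 0.72) with all 9 higher, H2-Q7 at 3.16 and the peptide transporter Tap1 at 1.62. Cxcl5 was 21.9-fold and Saa3 19.6-fold higher, while the inflammatory list as a whole had a median of 0.53 (0.42 to 0.60), with 16 of 24 higher and 7 lower. Matrix genes divided, with 25 of 34 higher and 9 lower, a median of 0.52 (0.50 to 0.54), Tnc at 2.94 (2.80 to 3.09) and decorin (Dcn) at -1.49 (-1.49 to -1.48). The median of all genes was 0.31 and TMM scaling shifted every ratio by -0.28, which brought the matrix and the inflammatory medians to 0.24.

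The adipogenic list had a median log2 ratio of -0.34 (-0.41 to -0.24) in the same fibroblasts, the oxidative stress list -0.69 (-0.72 to -0.67) and the Dpp4-high progenitor list -0.37 (-0.45 to -0.26). MHC class II genes had -0.81 (-0.87 to -0.74), again at low levels, with H2-Ab1 at 68.0 CPM labelled WT and 35.8 CPM labelled DTR beside 91.5 and 79.8 CPM in NK-like cells. Hypoxia and glycolysis genes had a median of 0.40 (0.36 to 0.48), near the 0.31 of all genes, which TMM scaling turned to 0.12, and the immediate early list had a median of 0.03 (0.01 to 0.07), which TMM scaling turned to -0.26. The lowest single genes were Inmt, a methyltransferase, 59.9-fold, the carboxylesterase Ces1d 85.2-fold, Hsd11b1 (ENSMUSG00000016194, chromosome 1, 193221634 to 193264075, minus strand), which regenerates active glucocorticoid, 41.8-fold, and the glutathione transferase Gsta3 28.6-fold lower. Mrgprg had 1 UMI against 65, a ratio of -7.00 (-12.32 to -4.47). The highest were the zinc finger gene Egr4, 160-fold, a leading gene of cluster 21, which held 0.0558% of the fibroblasts labelled WT and 10.2% of those labelled DTR, Cemip, which takes part in hyaluronan breakdown, at a log2 ratio of 5.64, the histone gene Hist1h4i, 34.4-fold, and Ciart, a circadian repressor, at least 48.8-fold with 288 UMIs against 0. H2-M2 (ENSMUSG00000016283, chromosome 17, 37480851 to 37483552, minus strand) had 1096 UMIs against 1, a ratio of 9.12 (6.64 to 14.43). Cluster 0 held 62.4% of the fibroblasts labelled WT, and clusters 1 and 7 held 42.9% and 30.3% of those labelled DTR. Endothelial-like cells were too few in the library labelled DTR for gene ratios.

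**Figure D3:**
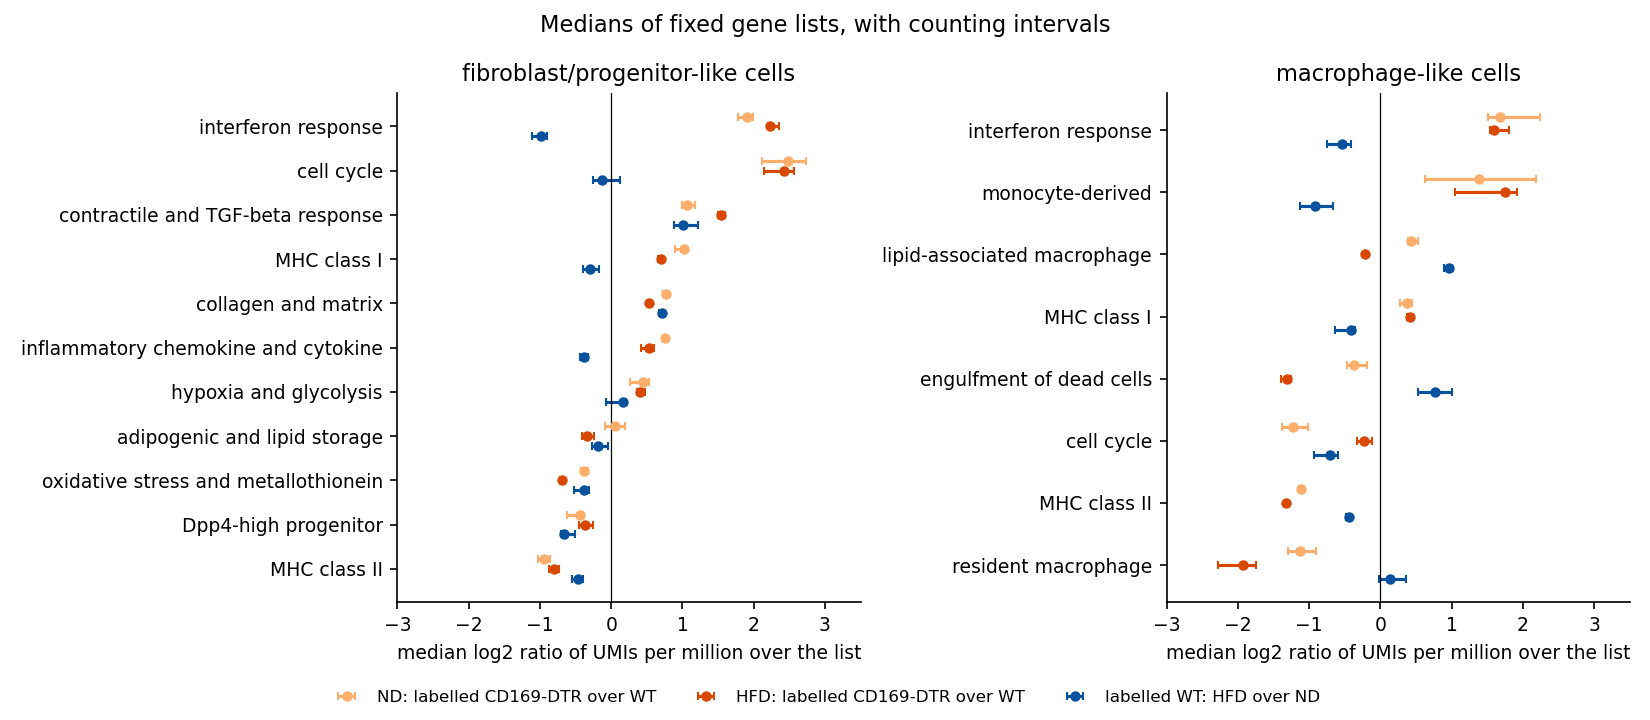
Median log2 ratio of selected fixed gene lists in fibroblast and progenitor-like and in macrophage-like cells, with 95% counting intervals. The series are the library labelled DTR over that labelled WT in each diet, and high fat over normal diet labelled WT. In fibroblast and progenitor-like cells the interferon list stood at 1.90 in normal diet and 2.23 in high fat diet.

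Macrophage-like cells of obese fat had a median log2 ratio of 1.59 (1.53 to 1.80) for interferon genes, with 20 of 21 higher in the library labelled DTR, Ifit3 at 3.68 and Mx1 at 3.51. Monocyte genes had a median of 1.75 (1.05 to 1.91), with Vcan, the matrix proteoglycan versican, 18.6-fold and Ly6c2 13.4-fold higher. Collagen and decorin UMIs in these cells were 488 CPM labelled DTR and 127 CPM labelled WT. Resident genes were lower in 14 of 15 cases, at a median of -1.93 (-2.28 to -1.74), with Cd209f at -7.87 (-9.19 to -6.82) and Lyve1 at -4.82. Engulfment genes were all lower, 13 of 13, at -1.30 (-1.40 to -1.25), and so were the 7 MHC class II genes at -1.33 (-1.34 to -1.32), with H2-Eb1 at -1.66 and H2-Aa at -1.63. Lipid-associated macrophage genes had a median of -0.21 (-0.23 to -0.19), with Apoe, a lipid carrier, at -2.49 and the fatty acid binding gene Fabp4 at -2.22, and this median was 0.17 over all phagocyte clusters. The immediate early list was at 0.57 (0.54 to 0.69). Clusters 12 and 31 held 27.0% and 24.1% of the macrophages labelled WT and cluster 3 held 52.7% of those labelled DTR, and TMM scaling shifted the ratios by -0.21.

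In obese fat, interferon genes were higher in the dendritic classes and cytotoxic genes lower in NK-like and T-like cells in the library labelled DTR. The cytotoxic list had a median log2 ratio of -1.05 (-1.09 to -0.99) in NK-like cells, with 7 of 10 lower, the chemokine gene Ccl4 at -1.70 and the perforin gene Prf1 at -1.30, and one of -0.65 (-0.85 to -0.43) in T-like cells, with 6 of 11 lower. Cluster 10, with cytotoxic leading genes, held 75.6% of the T-like cells labelled WT and 53.4% of those labelled DTR. The interferon list had medians of 1.63 (1.33 to 1.94) in type 2 and 1.05 (0.77 to 1.29) in type 1 conventional dendritic-like cells, with 9 of 10 and 9 of 11 genes higher. In NK-like cells it was 0.52 (0.25 to 0.80) with 4 of 9 higher, and in T-like cells 0.47 (0.25 to 0.69) with 5 of 10 higher, the rest within counting error. In type 2 dendritic-like cells Irf7 was 38.1-fold and Ifi27l2a 5.49-fold higher, and cluster 32 held 6.90% of those labelled WT and 43.1% of those labelled DTR. The highest NK genes were Ltb, 9.21-fold, Gadd45g, 5.98-fold, and Sdhaf1, 6.52-fold, and the lowest were Ly6c2, 6.67-fold, and Cma1, 4.8-fold, beside Ccl4. Cluster 39 held 1.37% of the NK-like cells labelled WT and 14% of those labelled DTR. Among list members in NK-like cells Ifi27l2a was at 3.55 (2.22 to 5.23) and Bst2 at 1.06. The B1 against B2 list had a median of -0.32 (-0.57 to -0.06) in B-like cells. Collagen and decorin UMIs in NK-like cells, which should lack them, were 409 CPM in the library labelled DTR and 249 CPM in that labelled WT. TMM scaling shifted the ratios by -0.29 in type 2 dendritic-like, -0.15 in T-like and -0.12 in NK-like cells.

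The comparison of diets in the libraries labelled WT asks how obese fat differs where, by the labels, resident macrophages were not targeted. Fibroblast and progenitor-like cells were 1.56-fold higher in high fat diet, T-like cells 1.72-fold higher and macrophage-like cells 2.20-fold higher as shares of their compartment. Mesothelial-like cells were 4.51-fold lower, group 2 innate lymphoid-like cells 1.68-fold, migratory dendritic-like cells 1.77-fold, type 2 conventional dendritic-like cells 1.61-fold, endothelial-like cells 1.47-fold, and type 1 conventional dendritic-like cells 1.30-fold lower. NK-like cells had a log2 ratio of 0.26 (0.01 to 0.52), neutrophil-like cells -0.57 (-1.22 to 0.06) and B-like cells -0.44 (-0.72 to -0.17), which turned to 0.26 under a stricter filter. The macrophage ratio of 1.14 was 0.29 over all phagocyte clusters and 2.10 without the cluster of low UMI counts, and the endothelial ratio of -0.55 was -0.96 with unnamed endothelial clusters included.

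In fibroblast and progenitor-like cells labelled WT, matrix and contractile genes were higher and interferon genes lower in high fat diet. Collagen and matrix genes had a median log2 ratio of 0.72 (0.67 to 0.74) with 31 of 34 higher. Mmp3 (ENSMUSG00000043613, chromosome 9, 7445822 to 7455975, plus strand) was 45.1-fold higher, at 149 CPM against 3.30 CPM, and Tnc 19.3-fold. Contractile genes had a median of 1.01 (0.88 to 1.21), with Ltbp2 at 3.98 and Acta2 at 3.57, which turned to -0.52 when every cell was scaled to the same total. All 20 measured interferon genes were lower, with a median of -0.98 (-1.11 to -0.91), Ifit1 at -3.1 and Iigp1 at -2.21. The inflammatory list was at -0.38 (-0.44 to -0.33), with the interferon-induced chemokine Cxcl10 at -2.65 and Cxcl14 at 1.43, the Dpp4-high progenitor list at -0.66 (-0.71 to -0.51) and the adipogenic list at -0.19 (-0.27 to -0.04). Other genes among the highest were the collagen gene Col8a1, 20.9-fold, and Mlana at 5.69 (3.82 to 8.75). The lowest were Tmem114 at -6.47 (-9.54 to -4.58), Ccl21a (ENSMUSG00000094686) at -6.21 (-9.28 to -4.31), Mmd2, 43.2-fold, the chloride channel gene Clic6, 11.5-fold, and the interferon-inducible GTPase Gbp5, 10.6-fold lower. The immediate early list was at 0.23 (0.18 to 0.28). Cluster 9 held 43.6% of these cells in normal diet and 11.4% in high fat diet, and cluster 0 12.7% and 62.4%. The Ccl21a ratio was 0.01 with doublets kept, and TMM scaling shifted all ratios by 0.11.

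Endothelial-like cells labelled WT had lower interferon genes in high fat diet, with 17 of 20 lower, a median log2 ratio of -0.73 (-0.86 to -0.58), Ifit1 at -1.88 and Irgm1 at -1.26. Angiogenic genes had a median of 0.22 (0.10 to 0.32), with Pgf at 1.16 and Nid2 at 1.13, and lipid handling genes 0.20 (0.13 to 0.28), with Fabp5, a fatty acid binding protein, 2.10-fold higher and the water channel gene Aqp1 at -0.65. Junction genes had a median of 0.00 (-0.08 to 0.10) and adhesion genes -0.17 (-0.36 to 0.04), both within counting error. The stress cytokine Gdf15 was 3.55-fold, Uchl1 3.59-fold and Creb5 2.46-fold higher. Cyp1a1 was at least 23.4-fold lower, with 0 UMIs against 92. The adipocyte genes Cfd (adipsin), Car3 and Retn (resistin) were 19.6-fold, 8.03-fold and 8.29-fold lower, and adipocyte transcripts over all non-immune cells were 30.5 CPM in high fat diet against 1099 CPM in normal diet.

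Among immune cells labelled WT, lipid-associated macrophage genes were higher in high fat diet, with 17 of 19 higher and a median log2 ratio of 0.97 (0.89 to 1.01) in macrophage-like cells. Of these cells, cluster 23, of low UMI counts, held 53.3% in normal diet and 8.86% in high fat diet, cluster 12, with Gpnmb and Trem2 leading, 6.61% and 27.0%, and cluster 31 7.93% and 24.1%. By UMIs, on which the ratios rest, cluster 23 gave 85031 and the cycling cluster 22 759331 of 1384146 in normal diet. In high fat diet cluster 12 gave 3388532 and cluster 22 1683484 of 7473283. The lipid receptor gene Trem2 was at 1.28 and the cathepsin gene Ctsl at 1.25, and these turned to -0.46 and -0.74 when every cell was scaled to the same total. Resident genes had a median of 0.14 (-0.02 to 0.35), with Cd209f at 1.95 and Igf1 at 1.36, and interferon genes -0.53 (-0.76 to -0.41). Over all immune cells the resident list without Siglec1 was at 1.94 (1.77 to 2.03) with 13 of 14 higher, and Siglec1 at 4.38 (2.45 to 7.46). In T-like cells cytotoxic and exhaustion genes had a median of 1.95 (1.42 to 2.44) with 8 of 12 higher, Ccl3 at 5.07 (3.17 to 8.13) from 97 UMIs against 2, and Gzma, granzyme A, lower at -3.99 (-5.03 to -3.1). Regulatory T genes had a median of -0.42 (-0.67 to -0.25), with Il2ra, the interleukin 2 receptor alpha chain, at -1.58 and Il1rl1, the receptor of interleukin 33, at -0.90. Type 2 cytokine genes were at -0.70 (-1.01 to -0.46) in T-like cells, with Calca at -1.07, and at -0.53 (-0.63 to -0.43) in group 2 innate lymphoid-like cells. In NK-like cells the cytotoxic list was at 0.41 (0.31 to 0.51). Ninj1, Cd69, an early activation marker, and the NF-kappaB inhibitor Nfkbia were the highest NK genes at 1.25, 1.15 and 0.89, and Spp1 and AY036118 were among the lowest at -2.38 and -1.54. The immediate early list was higher with them, at 0.29 (0.19 to 0.38) in NK-like cells with 10 of 16 higher, and at 0.25 (0.11 to 0.31) in T-like and 0.21 (0.07 to 0.32) in macrophage-like cells, the last at 0.039 over all phagocyte clusters. Cluster 15 held 63.7% of the T-like cells in normal diet and cluster 10 held 75.6% of those in high fat diet.

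The comparison of diets in the libraries labelled DTR asks the same where ablation was intended. Endothelial-like cells were 44.3-fold lower in high fat diet and NK-like cells 2.91-fold lower, while fibroblast and progenitor-like cells were 1.48-fold, macrophage-like cells 1.79-fold and T-like cells 1.37-fold higher. Mesothelial-like cells were 1.72-fold, group 2 innate lymphoid-like cells 1.88-fold, neutrophil-like cells 1.60-fold and B-like cells 1.51-fold lower, and the 3 dendritic classes lay within counting error, with log2 ratios of 0.30, -0.19 and 0.33. In fibroblasts, contractile genes had a median of 1.44 (1.36 to 1.51), with Ltbp2 at 4.22 and Acta2 at 3.51, and matrix genes 0.40 (0.37 to 0.42), with Tnc at 2.45 and Fmod, fibromodulin, at 2.16. The interferon list was at -0.88 (-0.94 to -0.78), with Irgm1 at -2.18 and Iigp1 at -2.01, and the inflammatory list at -0.66 (-0.67 to -0.60), with the B cell chemokine Cxcl13 at -4.45 and the eosinophil chemokine Ccl11 at -2.09. P4ha3, a collagen prolyl hydroxylase, was 58.7-fold and the mechanosensitive channel gene Piezo2 45.4-fold higher, and Mmd2 and the protamine gene Prm2 were at least 65.0-fold and 64.1-fold lower. In macrophage-like cells the interferon list was at -0.81 (-0.87 to -0.72), the resident list at -0.62 (-0.80 to -0.46), or -0.10 without Siglec1 over all immune cells, the lipid-associated list at 0.18 (0.17 to 0.27) and the immediate early list at 0.44 (0.41 to 0.47), which was 0.26 (0.21 to 0.30) in fibroblasts. NK-like cells had a cytotoxic median of -0.48 (-0.54 to -0.34), with Osgin1 at 1.89 and Prr5 at 1.68 among the highest genes, and the cholesterol exporter Abcg1 at -3.59 (-6.66 to -1.68) and Rapgef2 at -2.81 (-5.13 to -1.19) among the lowest. Different fibroblast clusters held most cells in each diet, cluster 4 in normal diet and clusters 1 and 7 in high fat diet, and TMM scaling shifted the macrophage ratios by -0.10.

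Set side by side, the genotype ratios of the 2 diets, which share no library, went together in most classes. Across 11058 genes in fibroblast and progenitor-like cells, Pearson's r between the log2 ratios was 0.69 and Spearman's rho 0.63, and across 8401 genes in macrophage-like cells r was 0.58. It was 0.69 in type 2 and 0.38 in type 1 conventional dendritic-like cells, 0.53 in NK-like, 0.27 in B-like and 0.15 in T-like cells, the 7 classes computed, with rho at 0.0088 in B-like and 0.076 in T-like cells. These correlations run across genes, which are not independent replicates. Where both intervals excluded 0, 87.8% of 5319 fibroblast genes and 86.7% of 2620 macrophage genes had the same sign in both diets. That share was 96.0% in type 2 and 87.0% in type 1 dendritic-like, 86.7% in NK-like, 68.9% in T-like and 61.1% in B-like cells. The fibroblast genes higher in both diets by the largest size were Ifi44, at log2 ratios of 5.67 and 5.67, H2-M2 at 5.27 and 9.12, Cxcl5 at 4.56 and 4.45, Saa3 at 6.02 and 4.29, and Egr4 at 4.29 and 7.32. Those lower in both were Ackr4 at -3.67 and -3.12, C7 at -2.68 and -3.95, the purine receptor gene P2ry1 at -2.66 and -3.45, Clic6 at -2.60 and -3.58, and Hsd11b1 at -2.24 and -5.39.

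**Figure D4:**
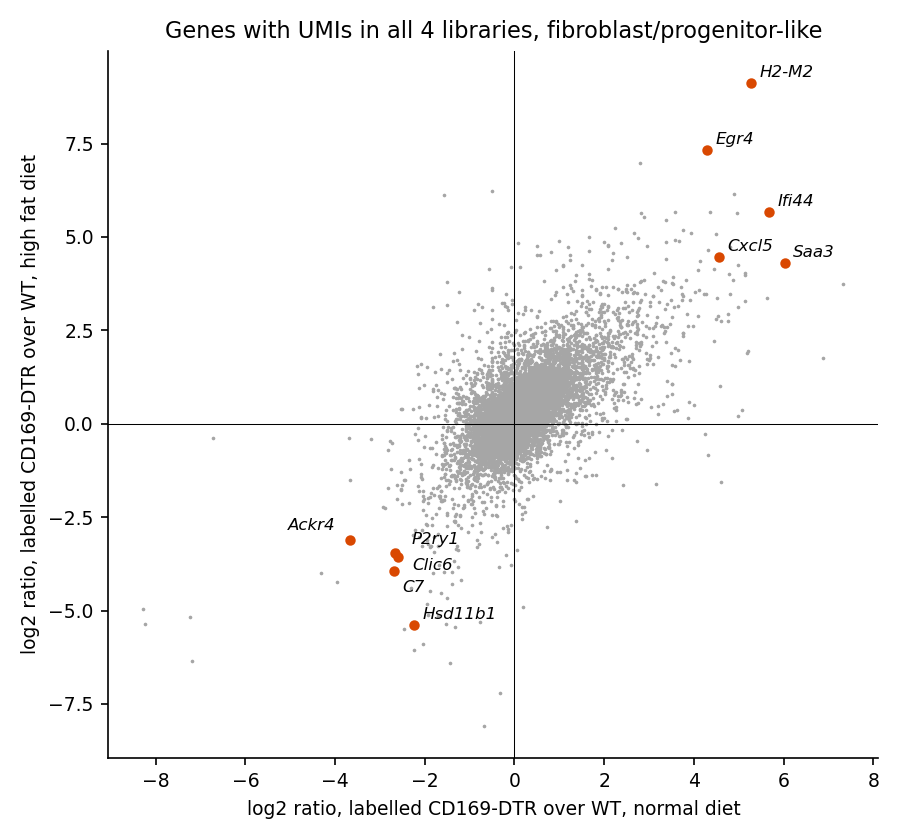
Log2 ratio of the library labelled DTR over that labelled WT in high fat diet (vertical) against normal diet (horizontal), each point a gene of fibroblast and progenitor-like cells with UMIs in all 4 libraries. Named genes such as Ifi44 and Hsd11b1 lie in the same direction in both diets.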

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

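Among the tests in this part, those of exchanged labels, of macrophage abundance, of dilution, of library yield and of dissociation stress were chosen after the result was seen, and those of interferon exposure, of the cell filter and of free RNA before it.

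Siglec1 was higher in the libraries labelled DTR, where its cells were meant to be lost. The sort gate on macrophage and monocyte surface markers may have removed many of these cells before sequencing. Whether the gate took a like part of them from each library was not tested, so a difference in gating stays open. More macrophage-like cells alone would leave the level within them alike, but within macrophage-like cells the log2 ratio was 3.35 in normal diet and 0.96 in high fat diet, both with intervals above 0. Exchanged labels would turn the other resident genes too. Their median over all immune cells was -1.81 in high fat diet, against an exchange if the gate acted alike in each library. In normal diet it was -0.17 with members going both ways. If genotype acts in 1 direction in both diets, an exchange in normal diet alone would give most genes opposite signs. Yet 87.8% (86.9 to 88.7) of fibroblast genes had the same sign. An exchange in normal diet alone thus stays open only if the effect of genotype turns with diet. Siglec1 is an interferon-induced gene. In both libraries labelled DTR, phagocytes in the upper part of the interferon list carried more of it than those in the lower part. The log2 ratios were 1.58 (0.96 to 2.22) and 1.36 (0.90 to 1.83). Those in high fat diet labelled WT did not, at -0.18 (-1.13 to 0.73). Within cluster 3 labelled DTR the ratio was 1.63 (0.76 to 2.58) in normal diet and 0.71 (-0.02 to 1.46) in high fat diet. In cluster 3 of high fat diet labelled WT it was 2.72 (-0.32 to 8.25), from 6 UMIs against 1. These few UMIs cannot show whether the libraries labelled WT and DTR differ in this. Interferon exposure may account for part of the excess, while an altered transcript from the inserted receptor stays open as untested.

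The near absence of endothelial-like cells in high fat diet labelled DTR was set against 3 explanations. Before any filter or clustering, 0.318% of its barcodes carried 3 or more of 8 endothelial markers, against 9.90% in the library labelled WT, which argues against the cell filter and the naming of clusters as the cause. Dilution by more fibroblasts would lower other non-immune cells alike, but barcodes with mesothelial markers were higher, at a log2 ratio of 1.69 (1.09 to 2.33). These were 94 barcodes against 31. The mesothelial-like share in the same comparison was -0.09 (-0.86 to 0.68) under a stricter cell filter. At a finer clustering it was -1.38 (-2.41 to -0.42), so that this 1 class cannot decide whether dilution had a part. Dilution alone would lower both classes alike, and the endothelial ratio was -5.41 (-6.33 to -4.62). Each mesothelial value lay above that interval, which argues against dilution as the whole of the drop in this library. With 1 library in the group, a poor yield of endothelial cells in this dissociation or sort and a loss in the tissue cannot be told apart. A loss of vessels in obese fat of these mice could be looked for in a further library or in sections, and remains an untested hypothesis.

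Interferon genes were mostly higher in the libraries labelled DTR in fibroblasts, macrophage-like and conventional dendritic-like cells of both diets, and in mesothelial-like and B-like cells of normal diet, the only diet measured there, while in NK-like and T-like cells 8 of 11 and 8 of 10 were higher in normal diet but 4 of 9 and 5 of 10 in high fat diet, and in normal diet those of endothelial-like cells went both ways and those of neutrophil-like cells lay at 0.16 (-0.07 to 0.65). Free RNA from fibroblasts would bring collagen and decorin in the same proportion, yet the interferon excess in NK-like cells was 63.6 times (55.6 to 71.7) what the fibroblast transcripts in them allow in normal diet and 17.6 times (13.4 to 21.9) in high fat diet. A stress response to dissociation would raise immediate early genes. The median of these genes was not higher in several classes with higher interferon medians, and in 2 of them few members were higher either. In T-like cells of high fat diet it was -0.04 (-0.16 to 0.10), but members went both ways, 3 of 17 higher and 4 lower, which decides nothing. In B-like cells of normal diet it was -0.22 (-0.41 to -0.04), with 1 of 17 higher and 5 lower, which argues against stress as the cause in every class. Stress stays open elsewhere. The immediate early median was 0.69 and 0.57 in macrophage-like cells of normal and high fat diet and 0.45 in NK-like cells of normal diet. In migratory dendritic-like cells of high fat diet it was 0.77. Members went both ways around -0.079 and 0.026 in fibroblasts and 0.0076 in mesothelial-like cells. The same held around -0.019 in endothelial-like cells of normal diet and 0.0001 and 0.011 in type 2 dendritic-like cells. An interferon response to cell death in the tissue is an untested hypothesis that dying cells and interferon-induced proteins in sections of further mice would check, and a difference between the mice or preparations behind each library stays open.

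Further results were noted because the genotype ratio pointed one way in normal diet and the other way in high fat diet; in each the difference was not tested. The NK-like share differed by -1.80 on the log2 scale, from 1.53 in normal diet to -0.27 in high fat diet. In high fat diet 242 of 2715 immune cells labelled DTR were NK-like and 1264 macrophage-like, against 293 and 519 of 2717 labelled WT. Among immune cells that were not macrophage-like, the NK-like part was thus higher labelled DTR in high fat diet too. The gate can set the macrophage share, so the turn with diet rests on the cells the share is taken over. The cytotoxic list in T-like cells differed by -1.21, from 0.56 to -0.65, while cluster 10 went from 36.3% labelled WT to 48.6% labelled DTR of these cells in normal diet and from 75.6% to 53.4% in high fat diet. Lipid-associated genes in macrophage-like cells differed by -0.65, from 0.44 to -0.21, but were 1.35 and 0.17 over all phagocyte clusters, both above 0. The medians of all genes there were 0.285 and 0.245. The high fat value, with 12 of 19 genes higher and 7 lower, thus lay under the level of all genes. It lay above the median of 0.0685 of random lists matched on mean expression, at percentile 84.5 among them. The immediate early list in fibroblasts differed by 0.10, from -0.08 to 0.03, but TMM scaling gave -0.18 and -0.26, the same direction in both diets. Mmp3 in fibroblasts differed by -3.68, from 2.97 to -0.71.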

How the results depend on the processing

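The alternatives over wider phagocyte or endothelial clusters, over immune cells for Siglec1 and without the low-UMI cluster were chosen after seeing the data. Of 300 comparisons of shares 259 stayed within their counting interval, 35 moved and 6 changed direction; for list medians these were 218, 76 and 5 of 299, and for named genes 791, 221 and 8 of 1020. The cause was not tested except where a class was redefined. For named genes the minimum of 200 UMIs only dropped genes and left the other values as they were. Thus 130 of the 791 were bound to stay within their interval. Siglec1 over immune cells was 7.83 CPM in normal diet labelled DTR, 2.23 and 8.57 CPM in high fat diet labelled WT and DTR. The log2 ratio of the macrophage share in normal diet, 1.58, became -0.20 at 200 genes and 20% mitochondrial UMIs, 2.70 at 500 genes and 5%, -0.25 with doublets kept, 1.84 and 1.06 at resolutions 0.8 and 2.5, 0.23 over phagocyte clusters and 2.66 without the low-UMI cluster. In high fat diet, 1.29 became 0.55, 1.47, 0.56, 1.45, 0.90 and 0.62 under the first 6 of these, and between diets labelled WT, 1.14 became 1.97 at 500 genes and 5%, 0.29 over phagocyte clusters and 2.10 without the low-UMI cluster. The endothelial ratio between diets labelled WT, -0.55, was -0.88 at 500 genes and 5%, -0.88 and -0.82 at resolutions 0.8 and 2.5, and -0.96 over wider clusters. At 500 genes and 5%, the NK ratio in normal diet was 1.19, the mesothelial and neutrophil ratios in high fat diet -0.092 and -0.74, the B ratio between diets labelled WT 0.26, Ccl3 in NK-like cells -0.46 and Birc5 in macrophages 1.5 (-0.40 to 4.58) in normal diet. At resolution 2.5 the mesothelial ratio in high fat diet was -1.38, and as a share of all cells the fibroblast ratio there was 0.50. With doublets kept, Ccl21a (ENSMUSG00000094686) in fibroblasts between diets labelled WT was 0.012, and 88.6% of macrophage genes had 1 sign in both diets. With each cell scaled to the same total, Acta2 in fibroblasts was -0.41 in normal diet and -0.52 between diets labelled WT, Spp1 in macrophages was -0.28 in normal diet, and Ctsl and Trem2 between diets labelled WT were -0.74 and -0.46. Under TMM, normal and high fat diet gave 0.67 and 0.24 for matrix, 0.66 and 0.24 for inflammatory and 0.96 and 1.26 for contractile genes in fibroblasts, and -1.17 and -1.54 for MHC class II in macrophages; in high fat diet the interferon medians were 1.95 in fibroblasts and 1.38 in macrophages and the fibroblast immediate early median -0.26, and 86.5% of fibroblast genes had 1 sign. With a minimum of 200 UMIs, the contractile median in high fat diet was 1.21, and the macrophage interferon and resident medians in normal diet were 2.37 and -0.47, over fewer genes. With stress, mitochondrial and ribosomal genes left out of the totals, the matrix median in high fat diet was 0.50, the inflammatory one in normal diet 0.74, and macrophage MHC class II -1.15 and -1.38. Over phagocyte clusters MHC class II was -1.26 and -1.52, cell cycle 0.35 and 0.21, and resident genes -0.74, engulfment 0.41 in normal diet and lipid-associated genes 0.17 in high fat diet. Leaving out a library was not possible with 1 per group. No paired analysis was run, each group has 1 library, and no result comes from a test. Depth limits genes with few UMIs most, and classes under 50 cells gave no ratios.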

Other observations

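The cell cycle results under a stricter filter and over wider phagocyte clusters, and the choice of the classes in this part, came after the values were seen.

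Mesothelial-like cells, the lining of the fat pad, had higher interferon, antigen presentation and chemokine genes in normal diet labelled DTR than in normal diet labelled WT. Of 21 interferon genes 20 were higher, with a median log2 ratio of 1.58 (1.41 to 1.78), led by the antiviral genes Rsad2 at 3.19 (2.93 to 3.45) and Ifit1 at 3.13 (2.79 to 3.48). MHC class II genes were higher as well, all 5 measured, at a median of 2.45 (2.11 to 2.77), with the invariant chain Cd74 at 3.08 and H2-Eb1 at 2.83; Cd74 stood at 896 CPM in these cells labelled DTR and at 110 CPM in NK-like cells of that library. The inflammatory list had a median of 0.71 (0.45 to 0.83) with 12 of 19 higher. Cxcl13, the chemokine for B cells, had 851 UMIs against 4, a ratio of 8.22 (6.86 to 10.10), and Cxcl5 was at least 51.4-fold higher with 110 UMIs against 0. In high fat diet too few mesothelial-like cells labelled WT were found for gene ratios.

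Macrophage-like cells had lower cell cycle genes in normal diet labelled DTR, in contrast to fibroblasts, and cluster 22, with the highest cell cycle score of the macrophage clusters, held 21.1% of them labelled WT and 6.80% labelled DTR. By UMIs, cluster 22 gave 759331 of 1384146 labelled WT and 888116 of 6513790 labelled DTR. The list had a median log2 ratio of -1.23 (-1.38 to -1.02) with 15 of 18 lower, led by Birc5, survivin, at -1.97 (-2.18 to -1.75) and the proliferation marker Mki67 at -1.84 (-2.04 to -1.63), and in high fat diet it had a median of -0.23 (-0.33 to -0.11) with 9 of 18 lower and 6 higher. Over all mononuclear phagocyte clusters the medians were 0.35 and 0.21, and Birc5 was at 1.5 (-0.40 to 4.58) under a stricter cell filter, an interval that holds 0, so that the direction in normal and high fat diet rests on which clusters are counted.

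Haemoglobin transcripts in non-immune cells stood at 4081 CPM in normal diet labelled WT, 422 CPM in normal diet labelled DTR, 2675 CPM in high fat diet labelled WT and 2.30 CPM in high fat diet labelled DTR. Over all immune cells together the direction was the opposite, at 36.8, 411, 146 and 324 CPM in the same order. In high fat diet B-like cells gave 3237 of the 6764 immune UMIs labelled DTR, at 18288 CPM against 35.1 CPM labelled WT. Macrophage-like cells of that diet were lower labelled DTR, at 232 CPM against 394 CPM. NK-like and T-like cells were lower too, with 0 UMIs each against 15 and 72. The immune direction in high fat diet was thus not shared by these classes. Endothelial markers over the non-immune cells were at 2094, 1005, 985 and 60.4 CPM.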
